A study of Homo sapiens with 12 samples.

How the data were processed

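RNA of NT2/D1 (NTERA2) cells, a human embryonal carcinoma line that differentiates under retinoic acid, was compared between cells carrying a short hairpin RNA against ZRF1 (gene symbol DNAJC2) and cells carrying a random hairpin. Cells were untreated (0 h) or had received 0.01 µM retinoic acid for 3 h. Each of the 12 Agilent 2-colour arrays held knockdown RNA in one channel and control RNA of the same time in the other. Each time had 3 biological replicates, and each replicate had a forward array, with the knockdown RNA in Cy5, and a dye-swapped array, with it in Cy3. Per the labels, 500 ng of total RNA went into each labelling reaction. The characteristics of the knockdown samples number the cell line from 1 to 6, whereas every title gives a single name, so all were treated as 1 line. The replicates were taken on different days, but which replicate number belongs to which day is not given in the sources used here.

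The deposited values were signed fold change ratios of Cy5 over Cy3, with ratios under 1 written as the negative inverse. The labels do not state this unit, and it was read from the values, which had 2 decimals and of which 0 lay between -1 and 1. Per the submitters' processing notes limma had been used, and its version, background correction and normalization method were not stated. Every array had a median log2 ratio within 1 rounding step of 0 (0.01 on the log2 scale) and an interquartile range of 0.154, so the arrays had been centred and scaled. No signal intensities accompanied the ratios, so no filter on signal over background was applied, and the number of arrays limits the precision.

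The ratios were converted to log2. By a rule fixed beforehand, the sign of the dye-swapped arrays was turned because DNAJC2 had the opposite sign on them, so that positive values mean higher in the knockdown. Of 41078 features, 78 were controls. Of the 41000 probes, 29341 had a single gene symbol, 33 had several and 11626 had none in the annotation used. Symbols and chromosomes came from a RefSeq gene table of the assembly GRCh38.p14, matched by Entrez number. Probes of a gene were averaged, which gave 18646 genes, 11036 of them measured by 1 probe and 7610 by 2 or more. Probes with no symbol were tested on their own. The forward and the turned swapped array of a replicate were then averaged, which left 6 values per gene.

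Linear models were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. The model had a coefficient for each time, and all 6 replicates shared 1 estimate of the spread per gene, with 4 residual degrees of freedom. Each SE given with a log2 ratio is the moderated SE of this fit. It rests on the spread shared by both times and does not show the spread of the replicates at 1 time. The comparisons were the knockdown effect at 0 h, the effect at 3 h, the difference of the effects (3 h minus 0 h) and the mean of the effects over both times. Values of p were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. Because no array set treated against untreated RNA, the response to retinoic acid itself was not measured. The replicate number was not used as a block, since the deviations of replicates with the same number from their time means correlated at 0.04, -0.03 and -0.30 across genes. A fit with the replicate block was run as an alternative.

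The gene lists, 21 in number, were written before the data were examined, as were the comparisons, the tests and the rule for named genes. They covered the retinoic acid response, the HOX clusters, pluripotency, neural genes, mesoderm and endoderm, developmental transcription factors, Polycomb complexes, H2A deubiquitinases with H2A ubiquitin ligases outside PRC1, heat shock and chaperones, the unfolded protein and integrated stress response, and ribosomal proteins. The others were the cell cycle, p53 targets and INK4, the interferon response, immediate early genes, TGF-beta, BMP and WNT targets, cholesterol synthesis, hypoxia and glycolysis, fibroblast and mesenchymal markers, epithelial and trophoblast markers, and blood and immune markers. Lists were tested with camera of limma, with a preset correlation of 0.01, which compares a list with all other genes. Camera with a correlation estimated from the data and fry were run beside it. The fry test asks whether a list's genes move, on balance, in one direction, and compares the list with no other genes.

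The rule for named genes took DNAJC2, then the 10 highest and 10 lowest log2 ratios among genes past the threshold whose replicates all moved the same way. It also took up to 4 members per list, those past the threshold with the largest change, or the 2 with the smallest p where a list had none. For a comparison with fewer than 5 genes past the threshold it took the 5 with the smallest p. Further list members named in the text were chosen after their values were seen.

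Alternatives fixed beforehand changed the normalization between arrays, the handling of the dyes, the replicates or time group in the fit, the treatment of probes, the estimate of the spread, the filter, the block and the minimum change. Added after the data had been seen were fits without 3 arrays of wide spread, with arrays rescaled by their width, with array weights and with regional medians subtracted. The gene fits without the wide arrays and with array weights used single arrays, a dye coefficient and a correlation within a replicate. The list tests without the wide arrays used the 9 other arrays and a dye coefficient, and took these arrays as independent. Their p values thus differ from the main ones in the model as well as in the arrays. An array was called wide when its range from the 1st to the 99th percentile of log2 ratios exceeded 1.2 times that of the median array.

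The procedure was tested on simulated data with 18646 genes and planted changes. With changes at both times, the mean effect recovered 55.2% of genes changed by 0.15 on the log2 scale, 88.1% at 0.3 and 98.5% at 0.6, with 5 false calls among 166. For the difference, with changes at 3 h alone, the recovery was 0%, 35.8% and 84.8%, with 3 false calls among 83. The effect at 3 h gave 14 false calls among 138 and the effect at 0 h 0 among 126. The simulated dye bias of a gene was the same on every array, so it cancelled in the replicate averages. False calls from a dye bias that is larger on the arrays of wide spread were therefore not covered. On unchanged data camera and fry called 0 of 84 list tests. The simulated genes varied independently of each other, so this cannot show how the preset correlation serves lists whose genes vary together. In the data the estimated correlation was 0.71 for ribosomal proteins, 0.25 for cholesterol synthesis and 0.19 for the stress response list. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.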

Results

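The data gave the ratio of knockdown to control RNA for 18646 genes on 12 arrays, 6 at 0 h and 6 at 3 h of retinoic acid. After each array was averaged with its dye swap, 3 replicate values per gene remained at each time. Replicate values correlated across genes at 0.469 to 0.563 among the 0 h replicates and at 0.322 to 0.557 among the 3 h replicates. Before turning, arrays of the same dye orientation correlated at 0.380 to 0.677, and the 2 arrays of a replicate at -0.108 to 0.189. A knockdown effect alone would make the latter clearly negative, so single arrays also held a sizeable dye bias. Genes are not independent replicates, so these coefficients only describe the arrays. Although interquartile ranges were equal, the range from the 1st to the 99th percentile of log2 ratios differed, and on 3 arrays it exceeded 1.2 times that of the median array. Those were the forward array of 3 h replicate 1, at 3.04, the swapped array of 0 h replicate 2, at 1.70, and the swapped array of 3 h replicate 3, at 1.10. These 3 are called the wide arrays.

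**Figure D1:**
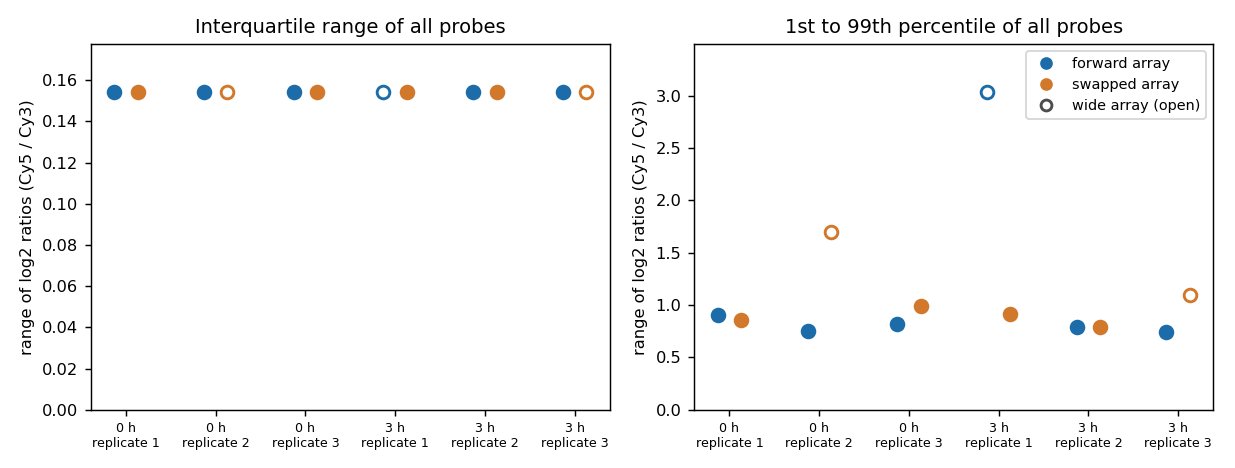
Range from the 1st to the 99th percentile of log2 ratios on each of the 12 arrays, by time, replicate and dye orientation. The forward array of 3 h replicate 1 reached 3.04 and the swapped array of 0 h replicate 2 reached 1.70.

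The first question was how far the hairpin lowered its target. DNAJC2, also called ZRF1 or MPP11, encodes a J-domain chaperone that sits on the ribosome and has also been described on chromatin. Its RNA was lower in the knockdown on 6 of 6 forward arrays, and the sign of the swapped arrays was set by this gene. Over both times DNAJC2 fell to 0.563 of the control level, a log2 ratio of -0.83 ± 0.15 (SE, n = 6; limma adjusted p = 0.0111). On forward arrays alone it was -0.94 and did not pass (adjusted p = 0.0647). At 3 h DNAJC2 fell, with a log2 ratio of -0.96 ± 0.21 (moderated SE, n = 3; adjusted p = 0.0348). That SE uses the spread shared by both times, and single 3 h arrays went from -2.73 to -0.39. At 0 h the ratio was -0.70 ± 0.21 and did not pass the test (adjusted p = 0.106). The call at 3 h ended on forward arrays alone (-1.30, adjusted p = 0.0903), with the replicate block (adjusted p = 0.0999) and with that time fitted alone (adjusted p = 0.144). It also ended without any single 0 h replicate and, at -1.03, without 3 h replicate 3, and the ratio was -0.63 without 3 h replicate 1. Without the 3 wide arrays, in a fit of single arrays with a dye coefficient, the ratios were -0.55 at 0 h (adjusted p = 1.83e-06), -0.51 at 3 h and -0.53 over both times. The difference between the times was -0.26 ± 0.30 (adjusted p = 0.783).

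**Figure D2:**
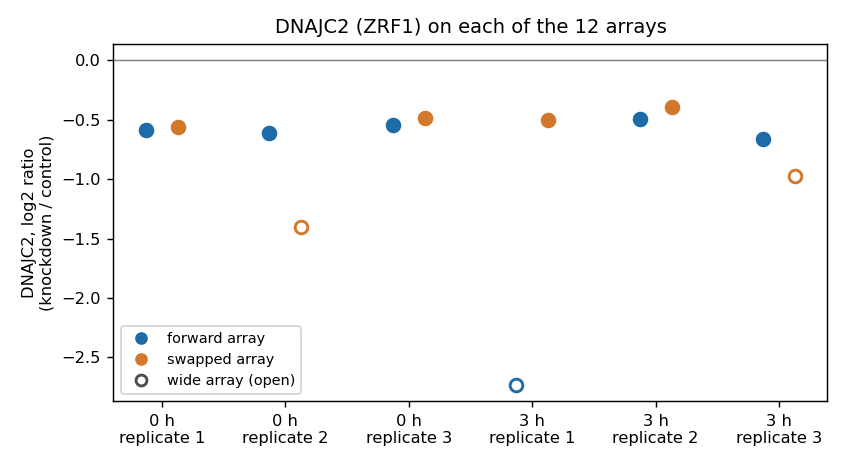
Log2 ratio of DNAJC2, knockdown over control, on each of the 12 arrays after dye-swapped arrays were turned. The sign of the swapped arrays was set by this gene, and the lowest values are -2.73 on the forward array of 3 h replicate 1 and -1.41 on the swapped array of 0 h replicate 2.

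The comparison at 0 h asked which genes differed between knockdown and control cells before retinoic acid. Among transcription factors, HESX1, a homeobox repressor of forebrain and pituitary development, fell by 0.83 ± 0.10 on the log2 scale (moderated SE, n = 3). FOXL2, a forkhead factor of the ovary, fell by 0.59. PCK2, the mitochondrial enzyme that makes phosphoenolpyruvate, fell by 0.80 and OXCT1, which activates ketone bodies, fell by 0.71. MX2, an interferon-induced GTPase, fell by 0.77 and CRYGD, a lens crystallin, by 0.73. The largest rise was that of NLRP2, a NOD-like receptor family member, at 2.16-fold or 1.11 ± 0.23 on the log2 scale. HEY1, a transcriptional repressor downstream of Notch, rose by 0.83 and MYH9, a heavy chain of non-muscle myosin, by 0.72. ARHGAP36, DDIT4, STC2 and SLC1A6 completed the 10 lowest, with log2 ratios from -0.67 to -0.57. TMEM204, TMEM125, NLRP2B, HTR3C, ASTE1, SHISA3 and TAGAP completed the 10 highest, with ratios from 0.66 to 1.00. As the rule for named genes required, each of these genes passed and moved the same way in 3 of 3 replicates, with adjusted p between 0.00394 and 0.0425. On the wide swapped array of 0 h replicate 2 NLRP2 stood at 2.29, against 0.68 to 1.14 on the other 0 h arrays.

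At 0 h, 5 of 20 measured genes of cholesterol synthesis rose and 0 fell, and 8 rose when adjusted over the list alone. The list median was 0.13 (camera adjusted p = 0.000244, adjusted p = 0.533 with an estimated correlation, fry adjusted p = 0.0546). LSS (0.30), MSMO1 (0.25) and CYP51A1 (0.20), all enzymes of the pathway, had the largest changes among those past the test. MVK, mevalonate kinase, averaged 0.19, from -0.12 on forward and 0.50 on swapped arrays. Among HOX genes, which pattern the body axis, 4 of 29 rose and 0 fell, and the numbers adjusted over the list alone were the same. They were the posterior genes HOXC9 (0.43), HOXD11 (0.40), HOXD10 (0.37) and HOXD9 (0.27), with a camera adjusted p = 0.00997, adjusted p = 0.533 with an estimated correlation and fry adjusted p = 0.0336 for the list. The median of the HOX list was 0.02 and its mean 0.07. Without 0 h replicate 3 the camera call on the HOX list ended (adjusted p = 0.0785). Among p53 targets and INK4 genes, 4 of 27 fell and 0 rose (camera adjusted p = 0.000527, adjusted p = 0.533 with an estimated correlation, fry adjusted p = 0.0343), and adjusted over the list alone 9 fell and 2 rose. TP53INP1 (-0.38), an autophagy and stress factor, CDKN2B (-0.27), an inhibitor of CDK4 and CDK6, ZMAT3 (-0.14) and SESN1 (-0.14) fell. Fibroblast and mesenchymal genes had 5 higher and 2 lower of 36 (camera adjusted p = 0.0453, adjusted p = 0.533 with an estimated correlation, fry adjusted p = 0.0475), or 8 and 3 adjusted over the list alone. THY1 (0.28), a surface glycoprotein, and the matrix genes COL5A2 (0.27) and LUM (0.25) rose, while CCN2 (-0.43), a target of YAP and TGF-beta signalling, fell. The call on the fibroblast list ended without the wide arrays (adjusted p = 0.141), with arrays rescaled by their width (adjusted p = 0.170), with the replicate block (adjusted p = 0.0575) and without 0 h replicate 2 or 3 or 3 h replicate 1 or 3. Of 68 ribosomal protein genes 0 passed the limma test, also when adjusted over the list alone, with a list median of 0.15 (camera adjusted p = 1.75e-05, adjusted p = 0.689 with an estimated correlation, fry adjusted p = 0.382). That median was 0.08 without the wide arrays, and medians on single arrays went from -0.37 to -0.21 on forward arrays and from 0.38 to 0.81 on swapped arrays. The camera call on them ended without 0 h replicate 2 (adjusted p = 0.170). By fry, but not by camera, immediate early genes were lower at 0 h (adjusted p = 0.0336). In the stress response list 7 of 30 fell and 0 rose, or 8 and 0 adjusted over the list alone, and it did not pass (camera adjusted p = 0.0671, adjusted p = 0.675 with an estimated correlation, fry adjusted p = 0.169). It passed without the wide arrays (camera adjusted p = 0.00208, with single arrays taken as independent), with 14 lower and 3 higher. With arrays rescaled by their width, on replicate averages as in the main test, it also passed (camera adjusted p = 0.00467).

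In the limma test, 1271 of 18646 genes passed at 0 h, 545 higher and 726 lower in the knockdown. Changes were small, with a median absolute log2 ratio of 0.19 among them, and 22 exceeded 1.5-fold. The number depended on single replicates, falling to 37, 60 and 57 without 0 h replicates 1, 2 and 3. It was 2396 and 712 without 3 h replicates 1 and 2, 3332 without the wide arrays, and 0 in limma with the replicate block (3257 at an unadjusted p under 0.05). More genes fell than rose, but on swapped arrays alone 2382 rose and 2045 fell, and without 0 h replicate 1 the numbers were 25 and 12. Of the 1271 genes, 53 had averages of opposite sign on forward and swapped arrays (4.17%, against 54.1% of all genes).

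The comparison at 3 h asked the same question after retinoic acid. PCK2 fell by 0.99 ± 0.16 on the log2 scale (moderated SE, n = 3), and PLAAT3, a phospholipase of the HRASLS family, fell by 0.82. CXCR4, a chemokine receptor expressed in definitive endoderm, fell by 0.68. NLRP2 rose 2.52-fold, by 1.33 ± 0.23, and TMEM204, a membrane protein of endothelial junctions, rose 2.36-fold, by 1.24 ± 0.18. EMC10, a subunit of a complex that inserts proteins into the endoplasmic reticulum membrane, rose by 0.87, SHISA3, an inhibitor of WNT and FGF receptor maturation, by 0.85 and IGFBP7, a secreted binding protein, by 0.71. MX2, OXCT1, HESX1, CRYGD, DDIT4 and STC2 were again among the 10 lowest, with log2 ratios from -0.80 to -0.64, together with DNAJC2. NLRP2B, TMEM125, HEY1, MYH9 and TAGAP were again among the 10 highest, with ratios from 0.73 to 0.90. As the rule for named genes required, each of these genes passed and moved the same way in 3 of 3 replicates, with adjusted p between 0.00393 and 0.0372. Some of these values were smaller without the wide arrays. There PLAAT3 stood at -0.43, CXCR4 at -0.41, DDIT4 at -0.42, NLRP2 at 0.88, EMC10 at 0.53, SHISA3 at 0.54 and IGFBP7 at 0.46, and PLAAT3 stood at -0.50 without 3 h replicate 1. TMEM204 and PCK2 stood at 2.90 and -2.35 on the forward array of 3 h replicate 1. On the 3 h arrays that are not wide TMEM204 went from 0.75 to 0.89 and PCK2 from -0.74 to -0.61.

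At 3 h, 8 of 20 cholesterol synthesis genes rose and 1 fell, or 13 and 1 adjusted over the list alone (camera adjusted p = 0.0012, adjusted p = 0.558 with an estimated correlation, fry adjusted p = 0.0353). HMGCS1 (0.48), MSMO1 (0.40), LSS (0.28) and SQLE (0.22), enzymes of the pathway, rose most among those past the test. Of 29 HOX genes 7 rose and 0 fell, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.0108, adjusted p = 0.558 with an estimated correlation, fry adjusted p = 0.0238). They included HOXD11 (0.44), HOXC9 (0.36), HOXD1 (0.33) and HOXD10 (0.27), and the HOX list had a median of 0.03 and a mean of 0.08. In the unfolded protein and integrated stress response list, 8 of 30 fell and 4 rose, or 15 and 6 adjusted over the list alone (camera adjusted p = 0.0284, adjusted p = 0.579 with an estimated correlation, fry adjusted p = 0.114). The camera call on it ended without 3 h replicate 1 (adjusted p = 0.219). DDIT4 (-0.65), an inhibitor of mTORC1, STC2 (-0.64), a secreted glycoprotein, ASNS (-0.64), asparagine synthetase, and SESN2 (-0.42), a leucine sensor, fell. Among p53 targets and INK4 genes, 7 of 27 fell and 4 rose, or 11 and 4 adjusted over the list alone (camera adjusted p = 0.00933, adjusted p = 0.558 with an estimated correlation, fry adjusted p = 0.0563). DDB2 (-0.48), a DNA damage binding protein, and TP53INP1 (-0.34) fell, while CDKN2A (0.47), the INK4 and ARF gene, and PLK2 (0.20), a stress-induced kinase, rose. Of 68 ribosomal protein genes 0 passed, also when adjusted over the list alone, with a list median of -0.18 (camera adjusted p = 0.000367, adjusted p = 0.760 with an estimated correlation, fry adjusted p = 0.444). That median was 0.01 without the wide arrays, and medians on single arrays went from -1.37 to -0.25 on forward arrays and from 0.19 to 0.40 on swapped arrays. The camera call on them ended without 3 h replicate 1 (adjusted p = 0.707). EN2, a midbrain and hindbrain homeobox gene, fell by 0.29, a value that was 0.01 without the wide arrays. Also without them ASNS stood at -0.34, DDB2 at -0.27, TP53INP1 at -0.21, CDKN2A at 0.28, HMGCS1 at 0.31, SQLE at 0.13 and HOXD1 at 0.22. By fry, but not by camera, retinoic acid response genes and fibroblast and mesenchymal genes were higher at 3 h (adjusted p = 0.0353 each).

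In the limma test, 2350 genes passed at 3 h, 1275 higher and 1075 lower, with a median absolute log2 ratio of 0.17, and 37 of them exceeded 1.5-fold. When the 3 h replicates were fitted alone 0 genes passed in limma and 4147 had an unadjusted p under 0.05. With 1 replicate left out the number fell to 946, 1490 and 980 without 0 h replicates 1, 2 and 3 and to 1465, 697 and 1094 without 3 h replicates 1, 2 and 3, whereas it was 3467 without the wide arrays. The balance also turned, with 580 higher and 682 lower on forward arrays alone, 496 and 598 without 3 h replicate 3, and 1729 and 1738 without the wide arrays, against 1672 and 1013 on swapped arrays. With the replicate block the number was 0 in limma (4687 at an unadjusted p under 0.05), and 109 of the 2350 genes had averages of opposite sign on forward and swapped arrays (4.64%, against 50.1% of all genes).

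Many genes passed at both times. Of 545 genes that rose at 0 h and 1275 that rose at 3 h, 468 were shared, where 37.3 would be shared by independent draws. Of 726 and 1075 that fell, 498 were shared, against 41.9. NLRP2, TMEM204, HEY1 and MYH9 were among those higher at both times and PCK2, MX2, OXCT1 and HESX1 among those lower, and 0 genes passed in opposite directions. Across genes the effects at the 2 times correlated at r = 0.588 and rho = 0.538, and at r = 0.749 without the wide arrays. Because both tests used the same estimate of the spread, the overlap is not that of independent tests.

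**Figure D3:**
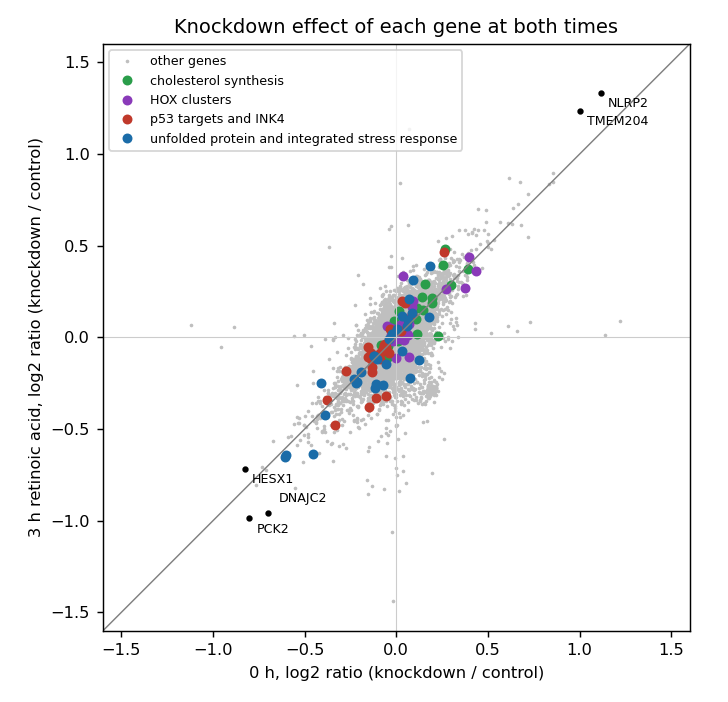
Knockdown effect (log2 ratio, knockdown over control) at 0 h on the horizontal axis and at 3 h on the vertical axis for 18640 genes, with 6 further genes outside the axes. Members of 4 gene lists are coloured, 5 genes with large effects are labelled, the diagonal marks equal effects, and the effects correlate at r = 0.588 across genes.

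The difference of the effects asked whether the knockdown acted differently after retinoic acid. In the limma test 0 genes passed, and 943 had an unadjusted p under 0.05, with a smallest adjusted p = 0.718. UBE2E1, a ubiquitin-conjugating enzyme, had the smallest p, with log2 ratios of -0.37 at 0 h and 0.49 at 3 h, a difference of 0.86 ± 0.12. The next were KEL, the Kell blood group protein (0.24 ± 0.04), ZNF143-AS1 (0.33 ± 0.05), ZFPM1, a cofactor of GATA factors (-0.17 ± 0.03), and GCOM1 (0.18 ± 0.03). At adjusted p = 0.718 none of these 5 passed. As lists, immediate early genes, which respond first to growth signals, had a higher knockdown effect at 3 h than at 0 h (median difference 0.07, camera adjusted p = 0.000801, fry adjusted p = 0.0163). Adjusted over the list alone 2 of 33 passed, both higher, and the list gave adjusted p = 0.220 with an estimated correlation. EGR1, a zinc finger factor of this group, had log2 ratios of -0.54 at 0 h and -0.26 at 3 h. EGR3 had -0.26 and -0.00. Ribosomal protein genes had a lower effect at 3 h than at 0 h (median difference -0.31, camera adjusted p = 2e-21). The list gave adjusted p = 0.885 with an estimated correlation and 0.573 by fry, and without the wide arrays the median difference was -0.05, where the camera call stayed (adjusted p = 5.65e-05), as it did with arrays rescaled by their width. No other list passed by camera. The response to retinoic acid itself was not measured on these arrays.

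The mean effect over both times asked which genes differed with the knockdown on average over the 6 replicates. The test itself did not require every replicate to move the same way. NLRP2 (1.22 ± 0.16, SE, n = 6), TMEM204 (1.12 ± 0.13), NLRP2B, a relative of NLRP2 (0.87 ± 0.05), TMEM125 (0.85 ± 0.04) and HEY1 (0.83 ± 0.05) rose most on the log2 scale. PCK2 fell most, by 0.89 ± 0.12, followed after DNAJC2 by MX2, which fell by 0.78 ± 0.07, HESX1 by 0.77 ± 0.07, CRYGD by 0.72 ± 0.04 and OXCT1 by 0.72 ± 0.04. SHISA3, MYH9, EMC10, TAGAP and IGFBP7, with ratios from 0.67 to 0.76, and PLAAT3, DDIT4, STC2 and ARHGAP36, with ratios from -0.69 to -0.62, completed the 10 genes at each end. As the rule for named genes required, each passed and moved the same way in 6 of 6 replicates, with adjusted p between 0.000482 and 0.0135. Some sizes rested in part on the wide arrays. On the forward array of 3 h replicate 1 NLRP2 stood at 2.96, TMEM204 at 2.90 and PCK2 at -2.35. On the arrays that are not wide NLRP2 went from 0.64 to 1.14 and TMEM204 from 0.75 to 0.96. There PCK2 went from -0.79 to -0.61 and CRYGD from -0.81 to -0.59.

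Over both times, 10 of 20 cholesterol synthesis genes rose and 1 fell, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.00048, adjusted p = 0.532 with an estimated correlation, fry adjusted p = 0.0133). INSIG1, which retains the sterol sensor in the endoplasmic reticulum, rose by 0.38 ± 0.07, HMGCS1 by 0.37, MSMO1 by 0.33 and LSS by 0.29. Of 29 HOX genes, 9 rose and 0 fell, and the numbers were the same adjusted over the list alone (camera adjusted p = 0.00722, adjusted p = 0.532 with an estimated correlation, fry adjusted p = 0.0103). HOXD11 (0.42), HOXC9 (0.40), HOXD10 (0.32) and HOXD9 (0.27) were the largest. The median of the HOX list was 0.02 and its mean 0.07, so the shift lay in part of the list. The stress response list had 13 lower and 6 higher of 30, or 15 and 7 adjusted over the list alone (camera adjusted p = 0.0455, adjusted p = 0.667 with an estimated correlation, fry adjusted p = 0.0637). The camera call on it ended without 0 h replicate 1 (adjusted p = 0.0607), 0 h replicate 3 (adjusted p = 0.0598) or 3 h replicate 1 (adjusted p = 0.0998). Among the members that fell were DDIT4 at -0.63, STC2 at -0.62, ASNS at -0.55 (-0.36 without the wide arrays), SESN2 at -0.41, and DDIT3 at -0.33 and CHAC1 at -0.23, which are known to be induced in the integrated stress response. Among those that rose were the endoplasmic reticulum chaperones PDIA4 at 0.29 (0.22 on forward and 0.35 on swapped arrays) and HSPA5 at 0.14 (0.23 and 0.05). Among p53 targets and INK4 genes, 11 of 27 fell and 4 rose, or 17 and 4 adjusted over the list alone (camera adjusted p = 0.00161, adjusted p = 0.532 with an estimated correlation, fry adjusted p = 0.0133). DDB2 (-0.40), TP53INP1 (-0.36) and CDKN2B (-0.23) fell, as did by a smaller amount CDKN1A (-0.09), the p21 inhibitor, and CDKN2A (0.36) rose. Fibroblast and mesenchymal genes had 12 higher and 5 lower of 36, or 15 and 6 adjusted over the list alone (camera adjusted p = 0.0301, adjusted p = 0.532 with an estimated correlation, fry adjusted p = 0.0133). COL5A2 and THY1 rose by 0.27 each, while CCN2 fell by 0.38 and TPM2, a tropomyosin, by 0.37. The call on this list ended when arrays were rescaled by their width (adjusted p = 0.0794) and without 0 h replicate 2 (adjusted p = 0.0674).

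**Figure D4:**
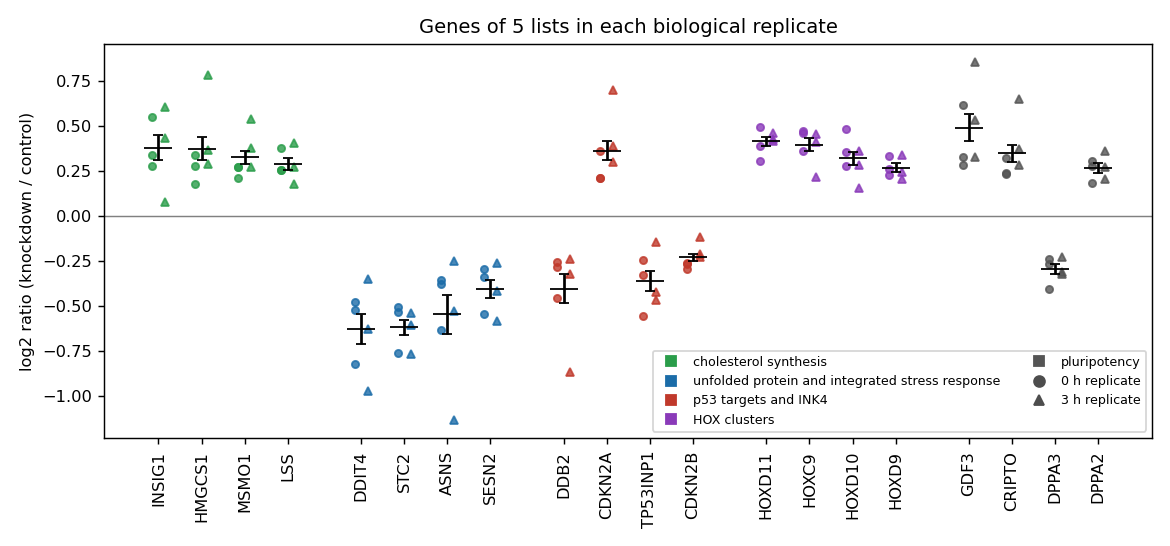
Mean knockdown effect over both times (log2 ratio, bars, with SE as error bars, n = 6) for 4 members of each of 5 gene lists. Cholesterol synthesis and HOX genes lie above 0, DDIT4, STC2, ASNS and SESN2 lie below 0, and the p53 and pluripotency members lie on both sides.

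The remaining lists did not pass by camera over both times. Except among heat shock and ribosomal protein genes, their members past the test went both ways. Of 32 pluripotency genes 4 rose and 6 fell, the same adjusted over the list alone. GDF3 (0.49) and CRIPTO (0.35), which act in NODAL signalling, and DPPA2 (0.27) rose, while DPPA3 (-0.29) fell. The core factors POU5F1 (-0.02), NANOG (0.02) and SOX2 (-0.04) did not pass. The median of this list was -0.02 and its mean 0.01, so they differed in sign. Of 30 retinoic acid response genes 7 rose and 4 fell, the same adjusted over the list alone, with CRABP2 (-0.35), a binding protein that carries retinoic acid to its receptor, NRIP1 (-0.20), a corepressor, LRAT (0.17) and RARB (0.15). By fry this list was higher over both times (adjusted p = 0.0282), though not without the wide arrays (adjusted p = 0.0697). Neural genes had 9 higher and 12 lower of 47, or 10 and 18 adjusted over the list alone, with ZIC1 (0.33), EN1 (0.27), TUBB3 (-0.28) and OTX2 (-0.19). Mesoderm and endoderm genes had 3 higher and 4 lower of 32, or 4 and 5 adjusted over the list alone, with EOMES (0.33), HAND1 (0.33) and CXCR4 (-0.60). Of 126 developmental transcription factors 18 rose and 21 fell, or 18 and 26 adjusted over the list alone, FOXL2 (-0.57) and BARX1 (-0.38) among them.

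Of 33 Polycomb genes 3 rose and 6 fell, the same adjusted over the list alone, with EZH2 (0.14), the H3K27 methyltransferase, PCGF6 (0.15), L3MBTL1 (-0.16) and BCOR (-0.15). Of 14 genes for H2A deubiquitinases and H2A ubiquitin ligases outside PRC1, 1 rose and 2 fell, the same adjusted over the list alone, with the ligases RNF168 (0.08) and UBR2 (-0.09) and the deubiquitinase USP44 (-0.17), of which RNF168 and UBR2 stood at 0.05 and -0.05 without the wide arrays. Heat shock and chaperone genes had 3 higher and 0 lower of 35, the same adjusted over the list alone, namely HSPB8 (0.24), HSPA2 (0.12) and BAG3 (0.09), although the list median was -0.02. Of 68 ribosomal protein genes RPL28 (0.13) alone rose, and 0 passed adjusted over the list alone. The list passed by camera with the preset correlation, as higher, without the wide arrays (adjusted p = 0.00565) and without 3 h replicate 1 (adjusted p = 0.00100). By fry it did not pass without the wide arrays (adjusted p = 0.312), and on all arrays camera with an estimated correlation gave adjusted p = 0.998. Cell cycle genes had 9 higher and 4 lower of 49, or 10 and 4 adjusted over the list alone, with CDK1 (0.20), E2F1 (0.15), CENPF (-0.24, or -0.15 without the wide arrays) and MCM10 (-0.16). Interferon response genes had 8 higher and 9 lower of 35, or 9 and 9 adjusted over the list alone, MX2, TAP1 (-0.37), IFITM1 (-0.26) and ISG15 (-0.23) among those that fell. The median of the interferon list was 0.02 and its mean -0.03. Immediate early genes had 8 higher and 10 lower of 33, or 9 and 10 adjusted over the list alone, with EGR1 (-0.40), SPRY4 (0.28) and IER3 (0.28), a median of 0.01 and a mean of -0.00. TGF-beta, BMP and WNT targets had 5 higher and 5 lower of 35, or 9 and 6 adjusted over the list alone, with SFRP1 (-0.36) and CCND2 (0.24). Hypoxia and glycolysis genes had 6 higher and 8 lower of 30, or 7 and 10 adjusted over the list alone, with PFKP (-0.29) and LOX (0.22). ENO2, an enolase of that list, averaged -0.51, from -1.03 on forward and 0.01 on swapped arrays, and -0.36 without the wide arrays. Epithelial and trophoblast genes had 2 higher and 3 lower of 26, the same adjusted over the list alone, with CDH1 (0.29), EPCAM (0.22, or 0.14 without the wide arrays), CLDN6 (-0.43) and KRT19 (-0.27). Blood and immune genes had 4 higher and 1 lower of 26, the same adjusted over the list alone, with HBG1 (0.25) and CD8A (-0.16).

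In the limma test, 4007 of 18646 genes passed over both times, 2015 higher and 1992 lower, with a median absolute log2 ratio of 0.12, and 27 exceeded 1.5-fold. Of the 3994 of them placed on a chromosome, 817 lay in neighbourhoods of genes that shared a direction, and among 888 genes of chromosome 7, 290 rose and 26 fell. Without 0 h replicates 1, 2 and 3 in turn the number was 2386, 2130 and 2286. With the replicate block it was 1846, and 528 of the 4007 genes had averages of opposite sign on forward and swapped arrays (13.2%, against 53.9% of all genes). Of probes with no single gene symbol 1131 passed.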

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

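The tests of the wide arrays, of the changed genes after regional medians were subtracted, and of the ribosomal protein genes on the arrays that are not wide were chosen only after the result was seen.

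Of the 7 groups of 6 arrays that could be tested for a single array apart from the rest, 7 had one. About 1 in 20 would be singled out by chance, but that share does not hold for values tied by rounding. Groups of different measures held the same arrays, so they were not independent. The widest ranges from the 1st to the 99th percentile of log2 ratios were 1.70 on the swapped array of 0 h replicate 2 and 3.04 on the forward array of 3 h replicate 1. DNAJC2 stood apart on the same arrays, at -1.41 and -2.73. The median log2 ratio stood apart at 0.0144 on the swapped array of 0 h replicate 2 and at -0.0144 on the swapped array of 3 h replicate 3, where the other arrays of the time were at 0, which is 1 rounding step. The interquartile range of the latter array was 0.154, again apart from the others by rounding alone.

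The first pattern was the spread of the 3 wide arrays. A larger knockdown effect in those replicates was argued against, if the DCP_22 control features match no study transcript, which was assumed and not checked. These features were stretched too, with a median ratio of 4.39 on the widest array to the other arrays of its dye orientation. Scaling of every array to a single interquartile range remains open as a candidate explanation. The highest interquartile range was 1.00 times the lowest over the 12 arrays while the outer percentiles differed, in line with such a scaling. Which property of those hybridizations would make the scaling act so was not tested.

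The second pattern was that ribosomal protein genes had a lower knockdown effect at 3 h than at 0 h, with a median difference of -0.31. Dye bias of the wide arrays may explain most of it, since the median difference without them was -0.0537. Camera with the preset correlation, on single arrays taken as independent, still called the list there (adjusted p = 5.65e-05). The fry test did not (adjusted p = 0.641), and on all arrays camera with an estimated correlation gave adjusted p = 0.885. A knockdown effect that changes with retinoic acid met the test written beforehand, with both dye orientations negative and the one nearer to 0 at -0.27, but each orientation holds a wide array, so that test could not separate the explanations. On the arrays that are not wide the higher of the orientations was 0.0319 ± 0.0526 (SE over arrays) and the other -0.168 ± 0.128, which leaves this explanation open. In the 9 other arrays these genes had a median dye coefficient of -0.33, below that of each of 10000 random lists of the same size.

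The third pattern was that many genes changed alike at both times, part of them beside each other on chromosomes. The largest median over 51 neighbouring genes was 0.15 in size, from UCN3 to DCLRE1C on chromosome 10 and lower in the knockdown in 6 of 6 replicates, beyond all 1000 shuffles of gene order (permutation p = 0.001, the smallest they can give), as a copy number difference between the cell lines could leave. Whether few neighbourhoods hold most of the changed genes was not decided by the windows beyond the shuffles, which held 20.5% of the genes past the test and 12.4% of the genes placed, but it was argued against by the 3109 of 4007 genes that still passed in the same direction after regional medians were subtracted. Dye bias left in the averages was argued against for the shift of chromosome 7 alone, as the median of its genes was positive in both orientations, at 0.0304 in the lower. This check does not cover the other changed genes, and 528 of the 4007 had averages of opposite sign on forward and swapped arrays. The titles name a single knockdown line and the characteristics number it from 1 to 6, and if it was a single line, an effect of the knockdown and other differences between the lines would be confounded for every gene.

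When knockdown and control were exchanged in some replicates, 1 of 32 splits, the real one, gave as many genes over both times as the 4007 found. The highest other split gave 0. That share is under 0.05 and the smallest that 32 splits can give, so chance was argued against there but not excluded. The result shows that the replicates agreed, which any difference between the cell lines shared by all replicates would also give. At 0 h the real number was 1271 and the highest other split gave 0, and at 3 h they were 2350 and 0, each in 1 of 4 splits, which are too few for a share under 0.05. For the difference, 10 of 10 splits gave as many as the real 0 (highest other 0), which says nothing, because no split can give fewer than 0.

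The difference between the times was also flagged for immediate early genes as a list, though its median was small, at 0.0652. Adjusted over all genes, 0 of the 33 members passed. UBE2E1 had effects of opposite sign at the 2 times, with a difference of 0.86, which was tested and did not pass (adjusted p = 0.718). The same held, at the same adjusted p, for GCOM1 (0.18), HOXB13 (0.11), KLF4 (0.11) and PSMB9 (0.12).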

How the results depend on the processing

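Fits without the wide arrays, with rescaled arrays, with array weights and with regional medians subtracted were chosen only after the result was seen. Subtracting array medians, scaling to equal median absolute deviation, robust spread, the median of probes, single probes, the filter on ratio size and regional medians left every count of genes within 1.5 times of the reported number. The numbers of genes past the test at 0 h and 3 h were 2892 and 3666 with quantile normalization, 2338 and 3567 with 12 arrays and a dye coefficient, 799 and 1262 on forward arrays, 2757 and 3600 with rescaled arrays and 4251 and 4127 with array weights. At 0 h it was 4427 on swapped arrays and 3332 without the wide arrays. With a minimum change of 1.2-fold in limma it was 0 at 0 h, 0 at 3 h (124 and 183 at an unadjusted p under 0.05) and 12 over both times. With the replicate block in limma it was 0, 0 (3257 and 4687 unadjusted) and 1846, and with 1 time fitted alone it was 1894 at 0 h and 0 (4147 unadjusted) at 3 h. Over both times it was 6785 on swapped arrays and 6375 with array weights. Leaving out each replicate in turn gave 37 (without 0 h replicate 1) to 2396 (without 3 h replicate 1) at 0 h, 697 (without 3 h replicate 2) to 1490 (without 0 h replicate 2) at 3 h, 2130 (without 0 h replicate 2) to 4237 (without 3 h replicate 1) over both times, and 0 to 1 (without 3 h replicate 3) for the difference. DNAJC2 at 0 h passed at -0.86 with quantile normalization, -0.82 on swapped arrays, -0.70 with that time alone, -0.55 without the wide arrays, -0.60 with rescaled arrays, -0.61 with array weights and, at -0.70, without 3 h replicate 1. At 3 h it failed the test at -1.30 on forward arrays, -0.62 on swapped arrays, and, with its value of -0.96 kept, with that time alone, a minimum change, the replicate block or without any 0 h replicate, and at -1.03 without 3 h replicate 3. Over both times it failed at -0.94 on forward arrays and -0.83 with a minimum change. Leaving out replicates, DNAJC2 ranged from -0.79 to -0.55 at 0 h and from -1.22 to -0.63 at 3 h. Lists past the test numbered 0 in all 4 comparisons with an estimated correlation (at most 1 at an unadjusted p under 0.05) and 1 by fry for the difference, and 3 to 5 at 0 h (3 without 0 h replicate 3) and 3 to 5 at 3 h (3 without 3 h replicate 1) with a replicate left out. At 0 h they numbered 4, of which 3 were higher, with array medians or with regional medians subtracted, against 5 and 4 in the main test. The sign reversed for BMI1 (0.0101) and MVK (-0.12) at 0 h on forward arrays, for RPL27A at 3 h (0.17) and ENO2 over both times (0.0120) on swapped arrays, and for EN2 at 3 h without the wide arrays (0.00662). The median of ribosomal proteins reversed without the wide arrays, to 0.00668 at 3 h and 0.0450 over both times, where leaving out replicates gave -0.0842 to 0.0757, the latter without 3 h replicate 1. The cause was not tested, except that a minimum change is a stricter test by construction. Camera with an estimated correlation also had little power, with 4 residual degrees of freedom. A filter on probes measured on 12 arrays removed nothing, and DNAJC2 has 1 probe, so these alternatives gave no value. How far signal over background limits the ratios is unknown, as no intensities were analysed here.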

Other observations

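The test of the chromosome neighbourhoods without the wide arrays and the subtraction of regional medians were chosen only after the result was seen.

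Chromosomes differed in the share of genes past the test over both times. On chromosome 7, 290 of 888 genes rose and 26 fell, with a median log2 ratio of 0.05 over its genes and medians from 0.04 to 0.06 in the 6 replicates. On chromosome 17, 51 of 1120 genes rose and 202 fell. On chromosome 10, which holds the window from UCN3 to DCLRE1C, 108 of 711 rose and 123 fell. Without the wide arrays the largest median over 51 neighbouring genes was 0.143. After the regional medians were subtracted, 3523 genes passed over both times, 3109 of them also among the 4007 found before, and 1003 passed at 0 h and 1837 at 3 h.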
